A study of Mus musculus with 12 samples.

How the data were processed

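Total RNA of embryonic day 16 mouse neocortex was isolated with Trizol, and libraries were prepared with the TruSeq RNA kit, per the labels' protocols. There were 12 libraries in 4 groups: 2 wild type and 4 homozygous knockout in the Nfia line, and the same numbers in the Nfib line. The labels do not say whether libraries came from separate embryos or litters. Without values per library, what spread the deposited p-values measure could not be checked, and the errors derived from them share this limit. The tools named are CASAVA 1.8.2, TopHat2 2.0.10, Cufflinks and Cuffdiff 2.1.1 with the mouse build mm9, per the submitters' processing notes. Counting details such as strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

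The analysis started from 1 table with 23352 gene rows. It holds FPKM averaged over each group by the authors, per the file headers. It also holds, for each line, the log2 fold of knockout over wild type with a p-value and a q-value, as deposited by the authors per the file headers. The table gives no value per library, so no spread, no depth and no test across libraries could be had, and the sums of FPKM are not a depth. The design fixed beforehand assumed values per library, to be tested with limma. Its stated fallback was used in its place: the authors' q at 0.05, with no test of this work.

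What the table holds was checked on its values. The q-values lie within 7.3e-05 for Nfia and 5.2e-07 for Nfib of Benjamini-Hochberg adjusted p-values over rows with a p under 1, 13736 rows for Nfia and 13729 for Nfib, and these rows count as tested. The smallest p in the deposited table is 5e-05, shared by 240 and 331 rows, so the smallest q is 0.00286 for Nfia and 0.00207 for Nfib and does not rank genes beyond that. The deposited fold lies a median of -0.012 and 0.022 from the log2 ratio of group FPKM. Spreadsheet errors stand in 1354 and 1378 fold cells, where a group is listed at 0 or missing. An entry of 0 can be a failed estimate: the abundant Eef1a1 is listed at 0 in the group labelled Nfia knockout and Tuba1a in both knockout groups. The table has 117 rows naming more than 1 gene, and near-identical genes such as the globins are uncertain.

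Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The gene lists, 28 in number, and the rule for named genes were fixed before the data were examined. Members higher, lower and not past the threshold were counted over all genes and with p adjusted over the list alone. The median fold of members at 1 FPKM or more in 1 of the groups was placed among 10000 random lists of the same size, drawn within 20 bins of mean FPKM. This percentile describes the lists and is not a p. Folds against other wild types used log2(FPKM + 0.1), and the correlation across genes log2(FPKM + 1), which understates changes of low genes. Chromosomes and gene order were taken from GENCODE M21 by symbol, matching 93.0% of rows. That annotation is of another build, so no coordinates are given.

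The difference between the lines was tested approximately, a choice made after seeing the data. The error of each fold was taken as its size divided by the normal deviate of its deposited p-value, raised to the running median over 501 genes of similar FPKM. A p at its smallest value gives an upper limit of the error. The difference was divided by both errors combined and adjusted by Benjamini-Hochberg. On simulated folds for 13554 genes, it called 2, 11, 26 and 33 of 50 genes with true log2 differences of 0.5, 1, 1.5 and 2, and 5 of 13354 unchanged genes. Of these 77 calls 5 were false, 6.49%. The simulation drew normal folds with errors at that same running median. It therefore takes the implied errors as true and does not give the false share among calls on the real folds. The test had low power, and a difference it misses is not shown to be absent. For list medians in the Nfia comparison, over 12354 genes, 11 of 200 simulated unshifted lists of 20 genes and 200 of 200 lists shifted by 0.5 fell outside the central 95%. The unshifted lists were drawn at random from the same genes as the reference lists, so a small share outside was fixed by construction. Members of a real list can move together, which the simulation leaves out. It therefore does not tell how often such lists leave the range without a knockout effect.

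The rule for named genes took the NFI genes, the 10 largest rises and falls per comparison at 1 FPKM or more, and up to 4 members per list with the smallest adjusted p, or 2 as values only where none passed. For the difference it took the 5 smallest adjusted p per direction. The text names a part of these, and a few genes the rule takes and the counts of the blood cell list are not reported here. Alternatives were stricter thresholds, filters and pseudocounts, pooled wild types and, chosen after seeing the data, the other line's wild types, genes off the sex chromosomes and genes with like wild types. Leaving out libraries, replicate blocks, other normalizations and splits of the samples could not be run on group values.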

Results

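RNA from microdissected neocortex of mouse embryos at embryonic day 16 was profiled in 12 libraries. Nuclear factor I (NFI) proteins are transcription factors that act on the switch of neural progenitors from making more of themselves to making neurons and glia. By titles and strain, the labels give 2 lines, one with a targeted Nfia allele and one with a targeted Nfib allele. The growth protocol names the Nfia allele 2 times, so the groups were taken from titles and strain. Each line had 2 wild-type libraries and 4 libraries labelled homozygous knockout. The comparisons ask which neocortical transcripts differ when NFIA or NFIB is disrupted, and whether both disruptions change the same transcripts. The values are the authors' group averages in FPKM (fragments counted relative to transcript length and library size), 1 per gene and group, so no spread between libraries can be given, and the read depth is unknown. The errors implied by the deposited p-values of the Nfia comparison had a median of 0.23 on the log2 scale at 1 to 5 FPKM and 0.14 at 20 to 100 FPKM. In the Nfib comparison these were 0.25 and 0.15.

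The targeted genes came first. Nfib transcript fell from 134 to 9.12 FPKM in the Nfib knockouts in the authors' deposited table, a log2 fold of -3.86 (q = 0.00207). In the same comparison Nfia rose from 24.3 to 54.4 FPKM, with a log2 fold of 1.18 (q = 0.00207) in the authors' deposited table that came to 0.69 when computed against the Nfia-line wild types. In the group labelled Nfia knockout, Nfia itself stood at 28.2 FPKM against 33.7 in its wild types in the authors' deposited table, a log2 fold of -0.27 that did not pass the threshold (q = 0.477). This is a value for the whole gene, so it does not check the label, and the group is called labelled Nfia knockout for that reason. Nfix fell in that group, from 165 to 108 FPKM (log2 fold -0.62, q = 0.00286) in the authors' deposited table. Its log2 fold in the Nfib knockouts was -0.17 (q = 0.853) in the authors' deposited table, and Nfic had log2 folds of -0.30 (q = 0.503) and -0.057 (q = 0.998).

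**Figure D1:**
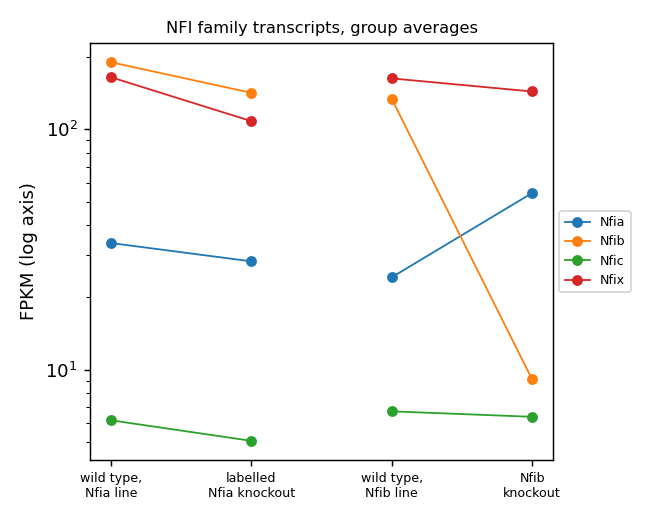
Group averages of the 4 NFI genes in FPKM on a log axis, with lines joining the wild types and knockouts of 1 line. Nfib falls to 9.12 FPKM in the Nfib knockouts, and Nfia stands at 28.2 FPKM in the group labelled Nfia knockout.

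In the group labelled Nfia knockout, 8 of 15 genes of striatal and other ventral forebrain neurons and 7 of 26 genes of maturing neurons were higher and none lower. Of 18 upper-layer neuron genes, 7 were lower and 2 higher, and of 16 intermediate progenitor genes 3 were lower and none higher. The other members of these lists did not pass the threshold. Of 13736 genes tested in the authors' deposited table, 520 passed q 0.05, 369 higher and 151 lower. At least a 2-fold change was reached by 167 of them in the authors' deposited table, 140 higher and 27 lower. Counts within gene lists and medians of folds were computed from that table.

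Upper-layer neuron genes gave 2 of 18 tested members higher, 7 lower and 9 not past the threshold (2 higher and 13 lower adjusted over the list alone), with a median log2 fold of -0.38 at percentile 0 of matched random lists. Pou3f2, a POU factor of upper-layer neurons, fell from 58.8 to 32.8 FPKM (q = 0.00286) in the authors' deposited table. The log2 folds in the authors' deposited table were Pou3f2 -0.86, Dok5 -0.61 and Unc5d -0.52. Intermediate progenitor genes gave 0 of 16 tested members higher, 3 lower and 13 not past the threshold (0 higher and 5 lower adjusted over the list alone), with a median log2 fold of -0.23 at percentile 0 of matched random lists. The lower members were Eomes, the T-box factor that marks these cells (-0.58), Insm1 (-0.54) and Mfap4 (-0.70) on the log2 scale in the authors' deposited table. Radial glia genes gave 0 of 24 tested members higher, 2 lower and 22 not past the threshold (2 higher and 2 lower adjusted over the list alone). The members lower in the authors' deposited table were the matrix protein gene Tnc (-1.14) and Mfge8 (-0.86). Cell cycle genes gave 0 of 32 tested members higher, 0 lower and 32 not past the threshold (4 at an unadjusted p under 0.05, and 0 adjusted over the list alone) by the authors' q-values. E2f1 and Ccnd2 had the smallest p in that list, with log2 folds of -0.47 (q = 0.130) and -0.34 (q = 0.209) in the authors' deposited table. Named log2 folds that moved by over 1.5 times when computed against the Nfib-line wild types came to Pou3f2 -0.25, Unc5d -0.12, Insm1 -0.33, Tnc -1.70 and Mfge8 -1.49.

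Neuronal maturation genes gave 7 of 26 tested members higher, 0 lower and 19 not past the threshold (9 higher and 0 lower adjusted over the list alone), with a median log2 fold of 0.15 at percentile 100 of matched random lists. Among the higher ones were Camk2a, a kinase of excitatory synapses, and Slc12a5, the chloride exporter of maturing neurons, with log2 folds of Camk2a 0.99, Slc12a5 0.98, Syn2 0.70 and Nrxn3 0.65 in the authors' deposited table. Striatum and ventral forebrain genes gave 8 of 15 tested members higher, 0 lower and 7 not past the threshold (11 higher and 0 lower adjusted over the list alone), with a median log2 fold of 0.89 at percentile 100 of matched random lists. Tac1, which encodes substance P, rose from 5.20 to 14.2 FPKM, and the homeobox gene Isl1 from 2.60 to 7.31 FPKM in the authors' deposited table. Log2 folds in the authors' deposited table were Tac1 1.44, Isl1 1.48, Zfp503 1.11 and Six3 1.11, Six3 standing at -0.20 against the Nfib-line wild types. Interneuron genes gave 9 of 22 tested members higher, 1 lower and 12 not past the threshold (11 higher and 1 lower adjusted over the list alone), with a median log2 fold of 0.45 at percentile 100 of matched random lists. Nkx2-1, the homeobox factor of the medial ganglionic eminence, rose from 0.457 to 1.86 FPKM in the authors' deposited table, and the folds of this group were Lhx8 2.85, Nkx2-1 2.01, Nr2f2 1.25 and Sst 1.20 on the log2 scale, with Nr2f2 at -0.62 against the Nfib-line wild types. Htr3a, a serotonin receptor subunit gene, decreased by 1.05 on the log2 scale in the authors' deposited table. Named log2 folds that moved by over 1.5 times when computed against the Nfib-line wild types came to Camk2a 0.53, Slc12a5 0.38, Syn2 0.35, Nrxn3 0.31, Tac1 0.37, Isl1 0.58, Zfp503 0.46, Nkx2-1 0.55, Lhx8 1.18, Sst 0.67 and Htr3a -2.40.

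Deep-layer genes moved both ways, with 2 of 19 tested members higher, 3 lower and 14 not past the threshold (3 higher and 4 lower adjusted over the list alone). Pcp4 was higher (log2 fold 0.97) and Tle4, a corepressor of corticothalamic neurons, lower (-0.59) in the authors' deposited table. Axon guidance genes gave 5 of 38 tested members higher, 5 lower and 28 not past the threshold (6 higher and 7 lower adjusted over the list alone), with a median log2 fold of -0.085 and a mean of 0.0083, which differ in sign, and the median was 0.0061 against the Nfib-line wild types. The secreted guidance cues Ntn1 (1.26) and Slit3 (1.17) and the receptor Nrp2 (0.82) were higher in the authors' deposited table, and the log2 fold of Slit3 computed against the Nfib-line wild types was -0.56. Cajal-Retzius genes gave 3 of 12 tested members higher, 1 lower and 8 not past the threshold (4 higher and 1 lower adjusted over the list alone), with log2 folds of Barhl2 1.05 and Calb2 0.86 in the authors' deposited table. Their median went from 0.26, at percentile 99.95, to 0.023, at percentile 66.07, against the Nfib-line wild types. Astrocyte genes gave 1 of 23 tested members higher, 1 lower and 21 not past the threshold (3 higher and 1 lower adjusted over the list alone), the glutamate transporter gene Slc1a2 being higher (0.63) and Bcan lower (-0.93) in the authors' deposited table. Oligodendrocyte lineage genes gave 1 of 15 tested members higher, 0 lower and 14 not past the threshold (1 higher and 1 lower adjusted over the list alone), the member that rose being Lhfpl3 (0.95) in the authors' deposited table. Thalamus and diencephalon genes gave 3 of 6 tested members higher, 0 lower and 3 not past the threshold (4 higher and 0 lower adjusted over the list alone) and hippocampus and cortical hem genes 2 of 14 tested members higher, 1 lower and 11 not past the threshold (5 higher and 2 lower adjusted over the list alone). The thalamus median, over only 3 members at 1 FPKM or more, went from 1.05 to 0.25 with pooled and 0.20 with Nfib-line wild types, both inside the central 95% of matched random lists. Lhx9, a member of both lists, had a log2 fold of 1.59 in the authors' deposited table, and folds computed from group FPKM of -1.09 against the Nfib-line wild types and -0.32 against the wild types of both lines pooled. Named log2 folds that moved by over 1.5 times when computed against the Nfib-line wild types came to Nrp2 0.17, Barhl2 0.34, Calb2 0.13, Slc1a2 0.12 and Bcan -1.92.

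Large rises outside the Y chromosome in the authors' deposited table included Fezf1 4.93, Lhx8 2.85, Nts 2.27, Ebf2 2.20 and Fgf15 2.18 on the log2 scale, Nts being the gene of the peptide neurotensin. Computed against the Nfib-line wild types, these came to Fezf1 0.44, Lhx8 1.18, Nts 2.04, Ebf2 1.91 and Fgf15 1.05, Fezf1 being at 0.101 FPKM in the Nfia-line and 2.26 in the Nfib-line wild types. Large falls in the authors' deposited table included Loxl1 -3.43, Dct -2.04, Hbb-y -1.52, Lars2 -1.46, Rn45s -1.42 and Fgfr4 -1.40, against Loxl1 -3.32, Dct -0.82, Hbb-y -0.10, Lars2 -1.53, Rn45s -1.99 and Fgfr4 -0.52 when computed with the Nfib-line wild types. Rn45s is the ribosomal RNA precursor, at 129.9 FPKM against 346, and Lars2 stood at 60.4 against 165 in the authors' deposited table. In the Nfib-line wild types and knockouts Rn45s was at 517 and 561 FPKM and Lars2 at 175 and 236, so only the group labelled Nfia knockout was low. With 1 average per group, a difference in library preparation cannot be told apart from an effect of genotype for these 2 genes. Sex-linked genes differed too: the Y-linked Ddx3y was at 0.0330 FPKM in the wild types and 7.29 in the group labelled knockout, and Xist, expressed from the inactive X, at 161 and 77.0 in the authors' deposited table. Against the wild types of the Nfib line, the list medians for this group came to 0.15 for striatum and ventral forebrain, 0.049 for interneurons, -0.11 for upper layers and -0.37 for astrocytes. Hippocampus and cortical hem went from 0.22 to -0.70 and deep layers from -0.073 to 0.22.

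In the Nfib knockouts, 12 of 26 astrocyte genes, 8 of 17 hippocampal and hem genes and 10 of 16 ventral forebrain genes were lower and none higher, and 4 of 16 oligodendrocyte lineage genes were lower and 1 higher. Higher genes were 7 of 32 of the cell cycle and 3 of 16 of intermediate progenitors, with none lower. Against the Nfia-line wild types the astrocyte median was -0.0081, at percentile 46.65 of matched random lists. Genes of other tissues moved in the same comparison, with a median log2 fold of 1.82 for choroid plexus and -0.64 for meninges and fibroblasts, the latter 0.23 against the Nfia-line wild types. The choroid plexus median rests on 4 members at 1 FPKM or more and the meningeal median on 10. Of 13729 genes tested in the authors' deposited table, 740 passed q 0.05, 292 higher and 448 lower. A change of at least 2-fold was reached by 271 in the authors' deposited table, 52 higher and 219 lower.

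Astrocyte genes gave 0 of 26 tested members higher, 12 lower and 14 not past the threshold (0 higher and 13 lower adjusted over the list alone), with a median log2 fold of -0.48 at percentile 0 of matched random lists. Bcan, the gene of the matrix proteoglycan brevican, fell from 9.39 to 1.40 FPKM, Hepacam, a glial adhesion gene, from 1.65 to 0.422 FPKM, and Id3 from 13.6 to 5.06 FPKM in the authors' deposited table. Their log2 folds in the authors' deposited table were Bcan -2.72, Hepacam -1.94 and Id3 -1.41, and that of Scrg1 was -2.82. Oligodendrocyte lineage genes gave 1 of 16 tested members higher, 4 lower and 11 not past the threshold (2 higher and 10 lower adjusted over the list alone), with a median log2 fold of -0.55 at percentile 0 of matched random lists. The basic helix-loop-helix factors Olig1 and Olig2 and the receptor Pdgfra, all of oligodendrocyte precursors, had log2 folds of Olig1 -1.19, Olig2 -1.14 and Pdgfra -0.83 in the authors' deposited table. The remaining lower member is also in the meninges and fibroblasts list. It stood at 1.59 FPKM in the Nfib knockouts, under the 7.59 of their wild types but above the 0.893 of the Nfia-line wild types. Named log2 folds that moved by over 1.5 times when computed against the Nfia-line wild types came to Bcan -1.64, Hepacam -0.57, Id3 -0.11, Scrg1 -1.23, Olig1 -0.62, Olig2 -0.64 and Pdgfra -0.52.

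Cell cycle genes gave 7 of 32 tested members higher, 0 lower and 25 not past the threshold (23 higher and 0 lower adjusted over the list alone), with a median log2 fold of 0.40 at percentile 100 of matched random lists. The proliferation marker Mki67 rose from 20.7 to 30.1 FPKM (q = 0.00532), and log2 folds in the authors' deposited table were Mki67 0.56, Rrm2 0.50 and Plk1 0.59. Intermediate progenitor genes gave 3 of 16 tested members higher, 0 lower and 13 not past the threshold (3 higher and 0 lower adjusted over the list alone), with a median log2 fold of 0.31 at percentile 100 of matched random lists. The proneural factors Neurog1 and Neurog2 had log2 folds of 1.69 and 0.77 in the authors' deposited table. Radial glia genes gave 6 of 25 tested members higher, 2 lower and 17 not past the threshold (7 higher and 3 lower adjusted over the list alone), with a median log2 fold of 0.064 at percentile 92.42 of matched random lists. That median was 0.19 with pooled wild types and 0.35 against the Nfia-line wild types, both at percentile 100. Gli3, a transcription factor of Hedgehog signalling, was higher (0.98), as was Id4 (0.87), while Tnc (-1.72) and Mfge8 (-1.38) were lower in the authors' deposited table. Deep-layer genes gave 5 of 19 tested members higher, 3 lower and 11 not past the threshold (9 higher and 7 lower adjusted over the list alone), and their median log2 fold of 0.26 and mean of -0.089 differed in sign. Tbr1, the T-box factor of early-born neurons, rose from 102 to 170.5 FPKM, and Sox5 and Nr4a2 had log2 folds of 0.97 and 0.96 in the authors' deposited table. Crym, which encodes a thyroid hormone binding protein, fell from 22.5 to 1.59 FPKM in the authors' deposited table. Named log2 folds that moved by over 1.5 times when computed against the Nfia-line wild types came to Mki67 0.12, Rrm2 0.19, Neurog2 0.49, Gli3 0.62, Tnc -1.14, Mfge8 -0.75, Tbr1 0.14, Sox5 0.34 and Crym -1.12.

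Upper-layer genes gave 0 of 18 tested members higher, 4 lower and 14 not past the threshold (2 higher and 6 lower adjusted over the list alone), with Dok5 -1.07, Lmo4 -0.88 and Pou3f1 -0.69 on the log2 scale in the authors' deposited table. Neuronal maturation genes gave 2 of 26 tested members higher, 4 lower and 20 not past the threshold (2 higher and 5 lower adjusted over the list alone), with a median log2 fold of -0.12 at percentile 0.03 of matched random lists, and -0.056 at percentile 4.07 against the Nfia-line wild types. The neurofilament genes Nefl and Nefm had log2 folds of -1.97 and -1.44, and Slc17a7, the vesicular glutamate transporter gene, 0.57 in the authors' deposited table. Striatum and ventral forebrain genes gave 0 of 16 tested members higher, 10 lower and 6 not past the threshold (0 higher and 12 lower adjusted over the list alone), with a median log2 fold of -1.37 at percentile 0 of matched random lists. Their log2 folds in the authors' deposited table were Tac1 -2.86, Six3 -2.81, Isl1 -2.24 and Zfp503 -1.66. Interneuron genes gave 0 of 22 tested members higher, 11 lower and 11 not past the threshold (0 higher and 11 lower adjusted over the list alone), with a median log2 fold of -0.68 at percentile 0 of matched random lists, with Htr3a -3.54, Nkx2-1 -2.44, Nr2f2 -1.78 and Npy -1.44 on the log2 scale in the authors' deposited table, Nr2f2 standing at 0.077 against the Nfia-line wild types. Hippocampus and cortical hem genes gave 0 of 17 tested members higher, 8 lower and 9 not past the threshold (0 higher and 13 lower adjusted over the list alone), with a median log2 fold of -0.90 at percentile 0 of matched random lists. Prox1, the homeobox factor of dentate granule neurons, fell from 3.32 to 0.576 FPKM and Wnt5a from 3.64 to 1.12 FPKM in the authors' deposited table. Wnt pathway genes gave 5 of 24 tested members higher, 7 lower and 12 not past the threshold (7 higher and 10 lower adjusted over the list alone). The Wnt agonist gene Rspo1 was lower (-3.39) and the Wnt antagonist gene Sfrp1 higher (0.94) in the authors' deposited table. These 2 genes do not stand for the list, which moved both ways. Rspo1 was at only 1.11 FPKM in the wild types and 0.106 in the knockouts. Axon guidance genes gave 6 of 37 tested members higher, 6 lower and 25 not past the threshold (9 higher and 8 lower adjusted over the list alone), among them Ntn1 (-1.29) and Slit3 (-1.09), both lower in the authors' deposited table, with Slit3 at 0.60 against the Nfia-line wild types. Named log2 folds that moved by over 1.5 times when computed against the Nfia-line wild types came to Lmo4 -0.42, Nefl -1.11, Tac1 -1.76, Six3 -1.35, Isl1 -1.30, Zfp503 -0.96, Htr3a -1.87, Nkx2-1 -0.79, Npy -0.86, Prox1 -0.67, Wnt5a -0.40, Rspo1 -0.53 and Sfrp1 0.49.

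Large falls besides Nfib itself in the authors' deposited table included Crym -3.82, Htr3a -3.54, Rspo1 -3.39, Htra1 -3.29, Cldn11 -3.23, Slc26a7 -3.22 and Dio2 -3.16 on the log2 scale, Dio2 being the enzyme that activates thyroid hormone. Computed against the Nfia-line wild types, these came to Crym -1.12, Htr3a -1.87, Rspo1 -0.53, Htra1 -1.01, Cldn11 0.048, Slc26a7 -2.46 and Dio2 -1.96. Large rises in the authors' deposited table included Xist 8.73, Ttr 8.10, Hmga2 2.79 and Kcne2 2.79, Hmga2 being a chromatin protein gene of early progenitors, and these came to Xist -0.91, Ttr 7.50, Hmga2 1.35 and Kcne2 2.23 with the Nfia-line wild types. Folr1 was at 1.18 FPKM and listed at 0 in the wild types in the authors' deposited table. Xist was at 0.207 FPKM in the wild types and 86.0 in the knockouts, and Ddx3y at 11.5 and 5.89 in the authors' deposited table. Against the wild types of the Nfia line, the list medians for the Nfib knockouts came to -0.13 for the oligodendrocyte lineage, -0.13 for hippocampus and hem, -0.18 for interneurons and 0.025 for deep layers. They were 0.25 for cell cycle, -0.44 for upper layers and 0.18 for the Wnt pathway, where the own wild types gave -0.20.

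**Figure D2:**
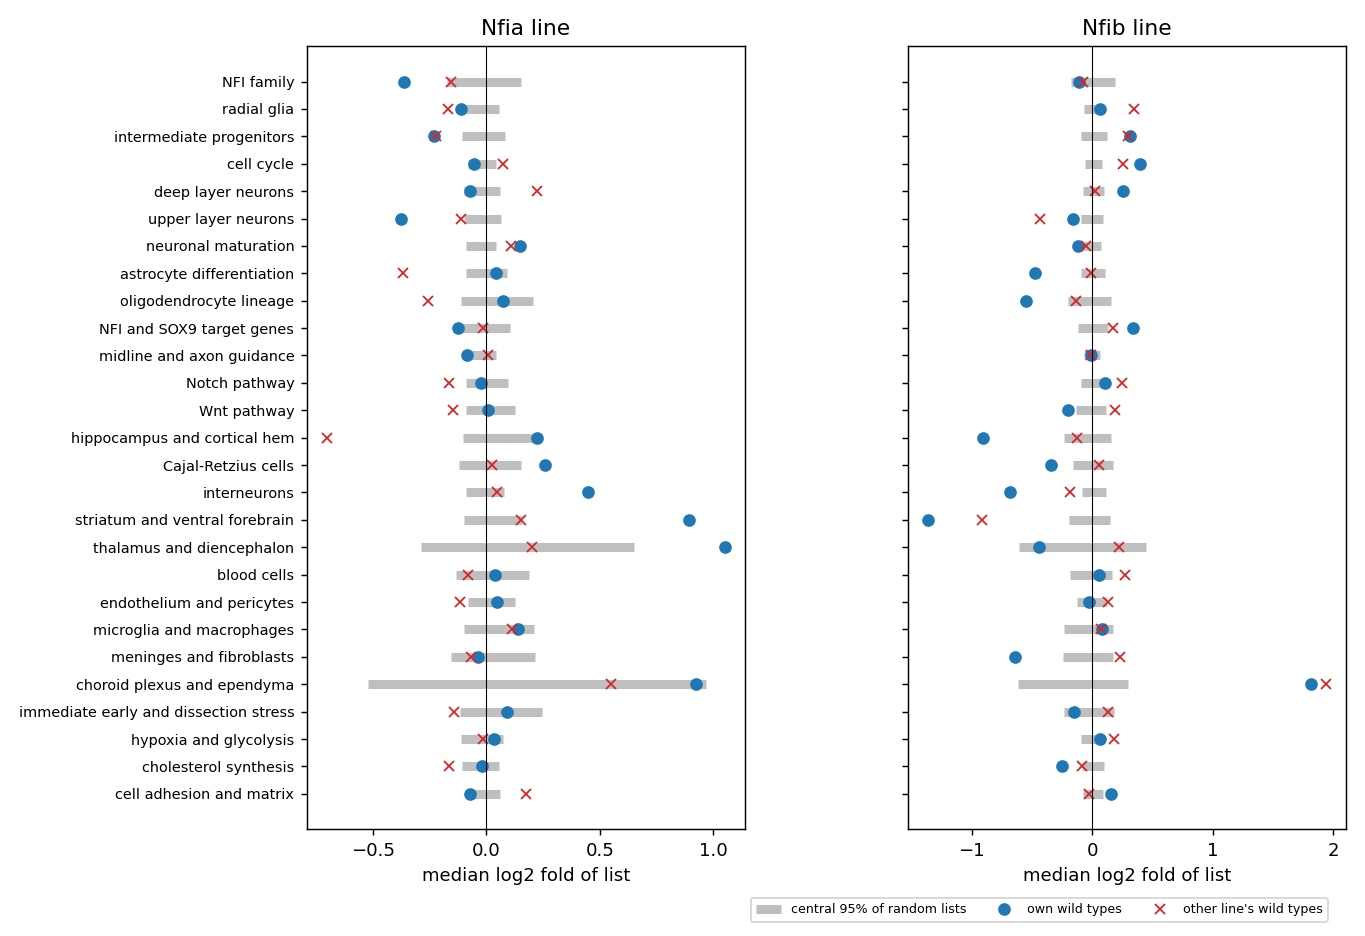
Median log2 fold (horizontal) of each gene list other than the sex-linked one in both lines, against the line's own wild types (circles) and the other line's wild types (crosses), with the central 95% of matched random lists against the own wild types as grey bars. The striatum and ventral forebrain median is 0.89 in the Nfia line and -1.37 in the Nfib line, and the astrocyte median of the Nfib line moves from -0.48 to -0.0081.

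The 2 comparisons have separate wild types. They shared a group of lower genes that included Tnc, Bcan and Dio2, and held a group that was higher in the one and lower in the other. Among 13559 genes tested in both, 182 passed q 0.05 in both. Of these, 52 were lower in both, where independent lists would give 4.70 (2-sided Fisher's exact p = 1.4e-40). They included Loxl1, a lysyl oxidase of elastic fibres (-3.43 and -2.70), Dio2 (-1.91 and -3.16), Tnc (-1.14 and -1.72), Bcan (-0.93 and -2.72), Cbs (-1.35 and -1.67) and Tle4 (-0.59 and -0.61) in the authors' deposited table. Another 23 were higher in both, against 7.56 for independent lists (p = 2.2e-06), among them Ttr (1.71 and 8.10), Apcdd1 (0.50 and 0.93) and Slc17a7 (0.44 and 0.57) in the authors' deposited table. The genes higher in the group labelled Nfia knockout and lower in the Nfib knockouts numbered 99, against 11.2 (exact p = 3.5e-67), and 8 went the other way, against 3.16 (exact p = 0.0142). These are exact tests over genes, which are not independent. Of the 99 opposite genes, 99 were higher in the Nfib-line than in the Nfia-line wild types, by a median log2 ratio of 0.84, and 56 were higher in the group labelled Nfia knockout than in the Nfib-line wild types. Choosing genes with opposite calls favours such a gap in part. Among genes whose wild types lay within 25% of each other, 34 were lower in both, 17 higher in both and 5 higher in Nfia and lower in Nfib, so the order of sizes turned, under a filter that removes opposite calls in part by construction. Against the other line's wild types the folds of Tnc were -1.70 and -1.14 and those of Bcan -1.92 and -1.64. Tnc lies near the targeted gene in both lines, so its shared fall is not separated from differences in DNA flanking the targeted alleles. Across 12255 genes of at least 1 FPKM the fold changes had Pearson's r = -0.0961 and Spearman's rho = -0.147, described across genes. Against the other line's wild types r was 0.232.

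**Figure D3:**
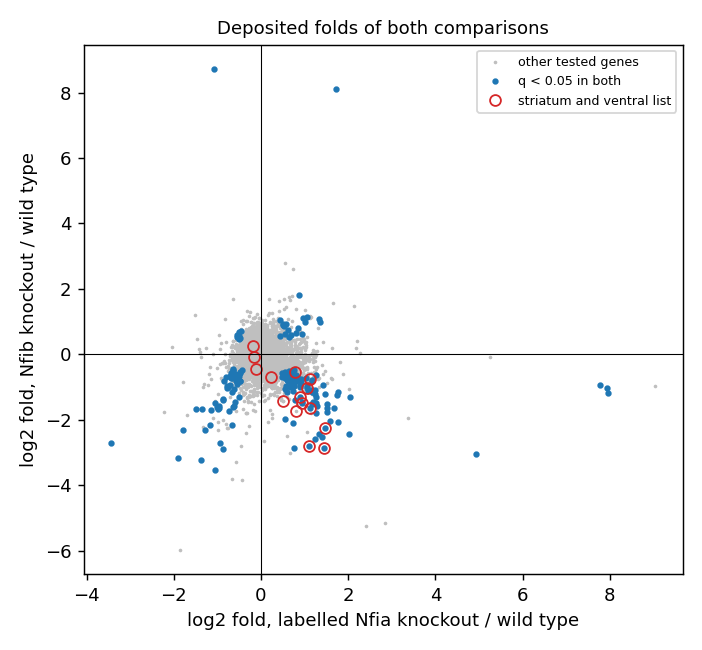
Log2 folds of the group labelled Nfia knockout (horizontal) and the Nfib knockouts (vertical) for tested genes of at least 1 FPKM, as deposited by the authors, with genes past q 0.05 in both in blue and the striatum and ventral forebrain list circled. The lower right part holds the genes higher in the one and lower in the other, 99 in the full table.

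A gene called in 1 comparison is not thereby shown to differ between lines. An approximate test of the difference, built from the errors that the deposited p-values imply, called 510 of 13554 genes at an adjusted p of 0.05, with the Nfia fold above the Nfib fold for 372 and below it for 138. Of 330 genes called in the Nfia comparison alone, 130 differed by this test, and of 524 called in the Nfib comparison alone, 188. The smallest adjusted p with the Nfia fold above belonged to Rasal1, Hap1, Ntn1, Adra2a and the vesicular GABA transporter gene Slc32a1. Their differences on the log2 scale were Rasal1 3.30, Hap1 2.20, Ntn1 2.56, Adra2a 2.46 and Slc32a1 1.57. With the Nfia fold below they belonged to Zkscan3, Abcc8, the semaphorin receptor gene Plxna4, Scrt2 and Zfp703, with Zkscan3 -1.09, Abcc8 -1.20, Plxna4 -1.17, Scrt2 -0.99 and Zfp703 -1.34. Against the other line's wild types the Nfia and Nfib folds were Rasal1 -0.38 and 0.36, Hap1 -0.26 and 0.22, Ntn1 0.94 and -0.96, Adra2a 0.25 and -0.21, Slc32a1 0.19 and -0.17, Zkscan3 0.10 and -0.050, Abcc8 0.27 and -0.10, Plxna4 0.23 and 0.0011, Scrt2 -0.13 and 0.15, and Zfp703 0.23 and 0.29. Both folds of Rasal1, Hap1, Zkscan3 and Abcc8 and the Nfia folds of Plxna4 and Zfp703 thereby changed sign.

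The wild types of the 2 lines were set side by side, with no test since each group has 1 value. Of 12380 genes of at least 1 FPKM, 41 were at least 2-fold higher and 3 at least 2-fold lower in the Nfib-line wild types, on log2(FPKM + 1). List medians of the log2 ratio, Nfib-line over Nfia-line wild types, were 0.60 for striatum and ventral forebrain, 0.61 for astrocytes, 0.66 for hippocampus and hem and -0.20 for upper layers.

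**Figure D4:**
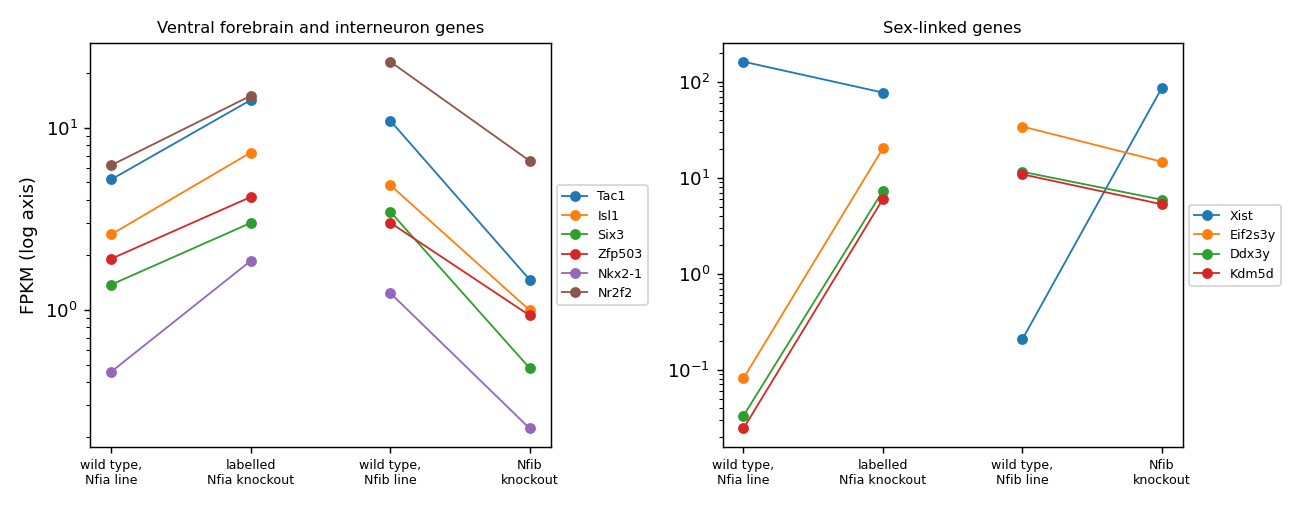
Group averages in FPKM on log axes for ventral forebrain and interneuron genes (left) and sex-linked genes (right), with lines joining the 2 groups of a line. Isl1 is at 2.60, 7.31, 4.84 and 0.993 FPKM from left to right, and Xist at 161, 77.0, 0.207 and 86.0.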

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

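The tests of explanations here, and the approximate test of the difference between lines, were chosen after the results were seen. Of 103 genes named with a fold, 98 could be compared and 64 had log2 folds that differed between the Nfia and Nfib comparisons at an adjusted p of 0.05. Most genes were named for a small q or a large fold, and 5 per direction by this same test. Selection therefore raises that share, which over all genes compared was 510 of 13554. Values below are the Nfia fold minus the Nfib fold on the log2 scale. For ventral forebrain and interneuron genes these were Tac1 4.30, Isl1 3.72, Zfp503 2.77, Six3 3.92, Nkx2-1 4.45, Nr2f2 3.04, Sst 1.24, Npy 1.52 and Slc32a1 1.57. Sex-linked genes gave Eif2s3y 9.15, Kdm5d 8.95, Ddx3y 8.72 and Xist -9.81. The targeted genes gave Nfia -1.45 and Nfib 3.42. Glial and progenitor genes gave Slc1a2 1.14, Hepacam 2.18, Id3 1.50, Olig1 1.19, Eomes -0.83, Insm1 -0.63, Neurog2 -1.04, Gli3 -1.21, Hmga2 -2.24, Mki67 -0.70 and Rrm2 -0.78. Layer and maturation genes gave Unc5d -0.79, Lmo4 1.08, Sox5 -0.97, Nr4a2 -0.94, Tbr1 -0.84, Pcp4 1.40, Crym 3.16, Camk2a 1.11, Slc12a5 1.46, Nrxn3 0.98, Nefl 2.51 and Nefm 1.38. Guidance, Wnt, hem and Cajal-Retzius genes gave Ntn1 2.56, Slit3 2.27, Nrp2 0.85, Plxna4 -1.17, Wnt5a 1.89, Sfrp1 -0.99, Prox1 3.11, Lhx9 3.63, Calb2 1.38 and Barhl2 1.50. The remaining genes gave Fezf1 7.98, Cdh4 -0.90, Cdh6 -1.14, Nts 2.23, Dct -2.26, Hbb-y -2.71, Lars2 -1.93, Rn45s -1.57, Ttr -6.39, Rasal1 3.30, Hap1 2.20, Adra2a 2.46, Zkscan3 -1.09, Abcc8 -1.20, Scrt2 -0.99 and Zfp703 -1.34.

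Of the tested striatum and ventral forebrain genes, 8 of 15 were called higher in the group labelled Nfia knockout and 10 of 16 lower in the Nfib knockouts. A difference between the wild types alone would leave the knockout groups alike, but their median log2 ratio, Nfia over Nfib line, was 1.46 (95% bootstrap interval over 15 members 0.77 to 2.05). With loss of Nfia as the whole cause, that group would stand as far above the Nfib-line wild types as above its own. Its median ratio to the Nfib-line wild types was 0.15 (0.039 to 0.46), under the median fold of 0.89 against its own wild types. The intervals in this paragraph measure the spread between member genes, not between embryos or dissections. With 1 average per group, these ratios describe the groups and do not decide the cause. A lowering by loss of Nfib remains open, since the Nfib knockouts also lay below the Nfia-line wild types, at -0.90 (-0.96 to -0.29). Amounts of ventral tissue that differ between all 4 dissections cannot be told apart from effects on ventral cells: interneuron genes outside the list moved along, with a median ratio of the knockout groups of 0.75, and each group has 1 value.

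Xist and Y-linked transcripts changed in both comparisons. A direct effect of either gene on Y-linked transcription is argued against by the wild types, whose smallest log2 ratio of Ddx3y, Eif2s3y and Kdm5d between lines was 6.45. Different shares of female and male embryos are consistent with the genes that escape X inactivation, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, chosen after their values were seen, whose median Nfib fold minus Nfia fold was 0.65, outside the -0.25 to 0.28 of matched random lists. The labels give no sex, but the Nfia-line wild types held Xist at 161 FPKM and Ddx3y at 0.0330, as female embryos would, the Nfib-line wild types 0.207 and 11.5, as males would, and the knockout groups both, at 77.0 and 7.29 for Nfia and 86.0 and 5.89 for Nfib. By these values sex differs along with genotype in both comparisons, and leaving out X and Y genes does not remove effects of sex on other genes.

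Nfia transcript was not called lower in the group labelled Nfia knockout. Its log2 fold was -0.27, with a 95% interval of -0.53 to -0.00105 from the implied error. Embryos with an intact Nfia gene, and a value that counts transcript from outside the deleted part, cannot be told apart with a whole-gene value, since values per exon were not analysed here.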

How the results depend on the processing

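The alternatives with the other line's wild types, genes off the sex chromosomes, genes with like wild types, the authors' folds, a recomputed adjustment, single-gene rows and the 5 FPKM filter on list medians were chosen after seeing the data, as were the difference test and the count of wild-type genes 2-fold apart. No paired analysis was possible because the deposited table gives 1 value per group. For the same reason the planned limma fits, their mean effect over both lines, normalizations, weights, blocks, left-out libraries, other splits, camera and fry were not run. Calls stayed within 1.5 times of 520 for Nfia and 740 for Nfib at 1 FPKM or more, with a recomputed adjustment, without X and Y genes and with single-gene rows. They came to 320 and 437 at q 0.01, 287 and 441 at 5 FPKM or more, 167 and 271 at 2-fold or more, and 201 and 258 where the wild types lay within 25% of each other, each keeping fewer genes by construction. Of the called genes, 460 and 644 had the same direction against the other line's wild types. Folds against the other line's wild types keep the same knockout averages, which favours the same direction by construction. Shared calls were 7 higher in both, 31 lower in both, 51 higher in Nfia and lower in Nfib, and 3 the other way at q 0.01; 11 higher in both, 31 lower in both, 52 higher in Nfia and lower in Nfib, and 7 the other way at 5 FPKM; 5 higher in both, 12 lower in both, 40 higher in Nfia and lower in Nfib, and 1 the other way at 2-fold; and 17 higher in both, 34 lower in both, 5 higher in Nfia and lower in Nfib, and 0 the other way with like wild types, a filter that removes opposite calls in part by construction. The correlation ranged from -0.106 to -0.0813 over the pseudocounts, filters and removal of X and Y genes, was -0.115 with the authors' folds and 0.232 against the other line's wild types; the cause was not tested. Wild-type genes 2-fold apart went from 44 to 113 with a pseudocount of 0.1 and 27 at 5 FPKM, and calls of the difference test from 510 to 301 at 0.01. Of the 28 list medians, 9 for Nfia and 13 for Nfib kept their direction and side of the random lists against the other line's wild types, and all did with pseudocounts of 1 and 0.1. The sign changed for 13 and 8 medians against the other line's wild types, 10 and 4 with pooled wild types, and 3 of 26 and 5 of 27 at 5 FPKM. Those outside the random range with the own wild types were, against the other line's wild types, midline and axon guidance 0.00606 and sex-linked -0.65 for Nfia, and Wnt pathway 0.18, Cajal-Retzius cells 0.059, meninges and fibroblasts 0.23, sex-linked 5.44 and cell adhesion and matrix -0.026 for Nfib. With pooled wild types they were, for Nfib, sex-linked 0.00111 and cell adhesion and matrix -0.00443, and at 5 FPKM Wnt pathway 0.39. Of 64 named genes called for Nfia and 75 for Nfib, log2 folds against the other line's wild types were over 1.5 times smaller for 25 and 40, over 1.5 times larger for 5 and 0 and of the other sign for 14 and 15. Those that changed sign were, on the log2 scale, Abcc8 0.27, Ddx3y -0.65, Hap1 -0.26, Lhx9 -1.09, Nefl -0.31, Nr2f2 -0.62, Plxna4 0.23, Rasal1 -0.38, Six3 -0.20, Slit3 -0.56, Xist 7.97, Zkscan3 0.10, Eif2s3y -0.75 and Kdm5d -0.84 for Nfia and Abcc8 -0.10, Cldn11 0.048, Dcn 0.11, Ddx3y 5.49, Fezf1 0.87, Hap1 0.22, Lhx9 0.60, Nr2f2 0.077, Rasal1 0.36, Slc1a2 0.00246, Slit3 0.60, Xist -0.91, Zkscan3 -0.050, Eif2s3y 6.35 and Kdm5d 5.44 for Nfib. With pooled wild types Lhx9 was -0.32 for Nfia and Ddx3y 0.029 for Nfib. Depth is unknown, so its limits cannot be given.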

Other observations

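The windows of genes over the genome and the values against the other line's wild types were chosen after the results were seen. Ttr, the thyroid hormone carrier that choroid plexus secretes, was at 0.346 FPKM in the Nfib-line wild types and 94.8 in the Nfib knockouts in the authors' deposited table, and the choroid plexus list gave 5 of 10 tested members higher, 0 lower and 5 not past the threshold (5 higher and 0 lower adjusted over the list alone). In the Nfia comparison the list gave 1 of 4 tested members higher, 0 lower and 3 not past the threshold (1 higher and 0 lower adjusted over the list alone). Meningeal genes gave 1 of 17 tested members higher, 8 lower and 8 not past the threshold (1 higher and 9 lower adjusted over the list alone) in the Nfib knockouts, the lower ones including Dcn at 0.274 against 2.13 FPKM in the authors' deposited table, and at a log2 fold of 0.11 against the Nfia-line wild types. Their median went from -0.64 against the own wild types to 0.23 against those of the Nfia line. In the Nfia comparison meningeal genes gave 0 of 11 tested members higher, 0 lower and 11 not past the threshold (0 at an unadjusted p under 0.05, and 0 adjusted over the list alone).

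Lists of other cells and processes were as follows. Endothelium and pericyte genes gave 0 of 22 tested members higher, 1 lower and 21 not past the threshold for Nfia and 0 of 22 tested members higher, 2 lower and 20 not past the threshold for Nfib, with the transporter gene Slco1c1 lower in both (-0.61 and -1.45 in the authors' deposited table). Microglia and macrophage genes gave 0 of 15 tested members higher, 0 lower and 15 not past the threshold (0 at an unadjusted p under 0.05, and 0 adjusted over the list alone) for Nfia and 0 of 18 tested members higher, 2 lower and 16 not past the threshold for Nfib. Cholesterol synthesis genes gave 0 of 16 tested members higher, 0 lower and 16 not past the threshold (0 at an unadjusted p under 0.05, and 0 adjusted over the list alone) for Nfia and 0 of 16 tested members higher, 2 lower and 14 not past the threshold for Nfib, where Fdps had a log2 fold of -0.48 in the authors' deposited table. Hypoxia and glycolysis genes gave 0 of 16 tested members higher, 0 lower and 16 not past the threshold (4 at an unadjusted p under 0.05, and 0 adjusted over the list alone) for Nfia and 0 of 16 tested members higher, 0 lower and 16 not past the threshold (3 at an unadjusted p under 0.05, and 0 adjusted over the list alone) for Nfib. Early-response and stress genes gave 1 of 15 tested members higher, 0 lower and 14 not past the threshold for Nfia and 2 of 13 tested members higher, 0 lower and 11 not past the threshold for Nfib. Notch pathway genes gave 0 of 21 tested members higher, 0 lower and 21 not past the threshold (0 at an unadjusted p under 0.05, and 0 adjusted over the list alone) for Nfia and 1 of 21 tested members higher, 0 lower and 20 not past the threshold for Nfib, and Wnt pathway genes 1 of 19 tested members higher, 1 lower and 17 not past the threshold for Nfia. The list of NFI and SOX9 targets from earlier work gave 1 of 10 tested members higher, 0 lower and 9 not past the threshold for Nfia and 2 of 12 tested members higher, 1 lower and 9 not past the threshold for Nfib. Cajal-Retzius genes gave 0 of 11 tested members higher, 0 lower and 11 not past the threshold (3 at an unadjusted p under 0.05, and 1 adjusted over the list alone) and thalamus and diencephalon genes 0 of 5 tested members higher, 1 lower and 4 not past the threshold for Nfib. Matrix and adhesion genes gave 0 of 26 tested members higher, 2 lower and 24 not past the threshold for Nfia and 4 of 26 tested members higher, 3 lower and 19 not past the threshold for Nfib, where Cdh6 and Cdh4 had log2 folds of 1.10 and 0.83 in the authors' deposited table. Computed against the other line's wild types, the Nfia fold of Slco1c1 was -1.03 and the Nfib folds were Fdps -0.14, Cdh6 0.48 and Cdh4 0.29. For Nfia, further medians that crossed the edge of the central 95% of matched random lists when set against the other line's wild types went from 0.045 to -0.12 for endothelium and pericytes, -0.019 to -0.16 for cholesterol synthesis, -0.023 to -0.16 for Notch pathway, 0.0080 to -0.15 for Wnt pathway and -0.073 to 0.18 for cell adhesion and matrix. Those of cell cycle (-0.056 to 0.075), oligodendrocyte lineage (0.074 to -0.26) and the NFI family (-0.37 to -0.16) crossed it too. For Nfib, further medians that crossed the edge of the central 95% of matched random lists when set against the other line's wild types went from -0.029 to 0.13 for endothelium and pericytes, 0.064 to 0.18 for hypoxia and glycolysis, 0.10 to 0.25 for Notch pathway, -0.34 to 0.059 for Cajal-Retzius cells and 0.15 to -0.026 for cell adhesion and matrix.

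Nfia and Nfib both lie on chromosome 4, and a hypothesis set down before the values were seen was that called genes lie near the targeted gene, as DNA flanking a targeted allele may differ between knockout and wild type. Among the 50 tested genes on each side of Nfib, 16% were called in the Nfib comparison against 5.31% of other genes (2-sided Fisher's exact p = 8.2e-05), 12 higher and 4 lower. Around Nfia, 7% were called in the Nfia comparison against 3.76% (exact p = 0.106), which leaves this line undecided. A check chosen afterwards set these beside 120 windows of 100 tested genes over the genome: 1 held as many calls as the Nfib neighbours and the highest held 16. The windows include that region. In the Nfia comparison the Nfia neighbours held 7 calls, and 12 of 120 windows held at least as many. The Nfib neighbours held 8 calls there, and 9 of 120 windows held at least as many. In the Nfib comparison the Nfia neighbours held 11 calls, and 7 of 120 windows held at least as many. The neighbourhoods of Nfia and Nfib share genes, so these counts are not separate checks. Tnc, lower in both comparisons, was among the called neighbours of Nfia in the Nfia comparison and of Nfib in the Nfib comparison. Nfia itself is among the called genes near Nfib, and genes with related expression can lie together, so the share is a hypothesis to follow up and not a measure of flanking DNA.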
